A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

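RNA abundance was measured in Saccharomyces cerevisiae on 4 arrays. 2 arrays were hybridised with material from cells with wild-type HSF1 and 2 with material from cells carrying hsf1-R206S/F256S, and all cells had been kept at 39 °C for 15 min. Per the labels, total RNA was copied into cDNA with an oligo(dT) primer and 33P-labelled dCTP, so each array carries 1 sample and there is no second colour. The deposited values are spot intensity values on a linear scale with 1 value per spot and array. They hold negative numbers on every array, which linear background subtraction gives, and their 4 means lie between 32.4 and 32.6, so each array appears scaled to a common mean. The software, the background method and the scaling step are not given in the sources used here. The array type is likewise not described in the labels, so intensities are in arbitrary units. The labels do not say whether the replicates were separate cultures, so the gene tests measure only the spread between these arrays. That spread may be technical.

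Each array had 6084 spots. GEO's platform annotation, which can be out of date, gave 1 gene symbol for 5523 spots, several for 0 spots and none for 561 spots. The symbols were checked through their gene identifiers against a current gene table of the reference strain, which matched 5523 of them and changed 0. Spots without a symbol are unnamed here, which does not mean that they lack a gene, and stayed in the tests. Averaging the spots of one gene on the log2 scale left 6051 genes and unnamed spots, of which 32 had more than 1 spot. The spots of those 32 can disagree. No genomic coordinates are printed, since the source of the probe sequences is not given in the sources used here.

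The quartiles of the 4 deposited columns differed by more than 5%, so the arrays were quantile-normalized with limma 3.58.1 in R 4.3.3, as set before the data were examined. Values below 0 after normalization were set to 0, an offset of 1.06 (the 5th percentile of the positive values) was added, and log2 was taken. Setting negative values to 0 was decided once they had been seen, and leaving them out was run as an alternative. The offset shrinks a true change of a dim gene on the log2 scale. It is also smaller than the noise SD of every array, so noise alone can give dim genes large log2 differences. Intensities printed with an SD are quantile-normalized values over 2 arrays per strain, before the offset. Folds are taken from the log2 means with the offset.

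Noise was estimated per array from the negative values, as the median of their absolute size divided by the normal quartile. The noise SD was 2.98 and 5.18 on wild-type replicates 1 and 2, and 2.80 and 3.89 on mutant replicates 1 and 2. A spot was taken as above background on an array when it exceeded 3 noise SDs. That held for 40.6% and 24.9% of the spots on the wild-type arrays and 61.2% and 41.5% on the mutant arrays. The number of arrays limits the precision, and spot counts are not depths. A gene not above background on any array of one strain has only a bound there. Its fold is given as "at least N-fold", the bright strain's mean against the dim strain's mean of, per array, the higher of the background limit and the gene's own value. No fold is given where that is under 1 or where both strains lie below background. The bound holds if the 4 arrays are on 1 scale. 2511 genes were above background on both arrays of at least 1 strain. That filter uses the strains and favours genes high in 1 of them. A filter without use of the strains kept 2220 genes whose mean log2 level over the 4 arrays was above the mean of the 4 limits, called bright here.

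Differences are mutant minus wild type. The main test was limma (lmFit and eBayes, two-sided) on all 4 arrays without a replicate block, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. It has 2 residual degrees of freedom and 1.54 prior ones. A fold rule without a p-value counted genes that differed by at least 2-fold and whose mutant arrays both lay on the same side of both wild-type arrays. Chance gives 33.3% of genes without overlap in either direction. 22 gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera at the preset correlation compares members with the other genes, and its precision comes from the number of genes. Its p-values therefore do not measure how a list varies between arrays or cultures. Camera at an estimated correlation takes its p-values on the 2 residual degrees of freedom, so it can miss lists whose members are not correlated. The p-values were adjusted over the 22 lists. For each list, members were also counted past an adjusted p of 0.05 over the list alone. The lists come from general knowledge of yeast. 5 further lists and 4 subsets of fixed lists were chosen after seeing the data, with p-values adjusted over these together.

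The scripts were tested on simulated data, 10 runs of 6051 genes with 200 genes changed and noise taken from these arrays. The changed genes were drawn only from spots well above the median intensity. The proportional noise (SD 0.38, log2) was taken from bright spots. Recovery of dim genes was not tested. The main adjusted test recovered 0% of genes changed 4-fold and 0% of genes changed 16-fold, and the fold rule recovered 99.4% and 100% of them. In each run 784.5 unchanged genes on average also met the fold rule, 163.9 of them above background. limma with an intensity trend on genes above background recovered 96.4% and 99.7% and called 7.5 unchanged genes per run, and on bright genes 96.9% and 99.7% with 8.3 unchanged genes. The camera test called a changed Hsf1 target list in 100% of runs and on average 0 of 13 unchanged lists. The simulated noise was independent for each spot and array, so list members did not vary together. The simulation therefore cannot show how often camera calls unchanged lists whose members are correlated. Those trend fits were chosen after seeing the data and are reported beside the main test.

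Named genes follow a rule set before the data were examined. It takes the 10 lowest-p genes per direction past the adjusted threshold, the 10 largest decreases and increases past the fold rule among genes above the median level, HSF1, every Hsf1 target, and up to 4 members of each other list by size of difference. Other genes named are said to have been chosen after their values were seen. The alternatives were median scaling, no normalization, cyclic loess, other offsets, removal of dim genes, an intensity trend, robust moderation, a replicate block, the brightest spot per gene, a 1.5-fold threshold, other set tests and leaving out each array. Alternatives added after seeing the data were genes above background, bright genes, spots at exactly 0 left out, values below 0 left out, array weights, and the Msn2/Msn4 list without shared members. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out.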

Results

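Transcript levels were measured in yeast cells held at 39 °C for 15 min. 2 arrays came from cells with wild-type HSF1 and 2 from cells with hsf1-R206S/F256S. HSF1 (YGL073W) encodes the heat shock transcription factor, an essential activator that binds the promoters of chaperone genes, and this allele changes 2 of its amino acids. The comparison asks which transcripts differ between the strains under heat. No unheated sample was analysed here, so the differences are between strains at 1 temperature and say nothing of induction. Median deposited intensities were 6.28 and 5.86 on wild-type replicates 1 and 2 and 11.9 and 8.49 on mutant replicates 1 and 2. Values at or below 0 made up 17.1% and 23.9% of the spots on the wild-type arrays and 7.12% and 14.4% on the mutant arrays. Across 6051 genes, which are not independent replicates, the mutant arrays correlated with Pearson's r of 0.813 and the wild-type arrays with 0.687. Wild-type replicate 1 correlated more closely with the mutant arrays, at 0.745 and 0.753. Over 2220 genes bright by their mean over all 4 arrays the order turned, with 0.808 between the wild-type arrays and 0.722 and 0.771 between wild-type replicate 1 and the mutant arrays. Wild-type replicate 2 had the highest noise SD, 5.18 against 2.80 to 3.89 on the other arrays.

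The genes that Hsf1 is known to drive fell together in the mutant. Of 30 measured Hsf1 targets, 29 had a lower mean in the mutant and 27 met the fold rule downward, with a median log2 difference of -2.78. The lowest log2 difference with the offset was that of HSP26 (YBR072W), a small heat shock protein that binds unfolding proteins. Its normalized intensity was 199 ± 5.80 (SD, n = 2) in the wild type and 4.75 ± 0.806 (SD, n = 2) in the mutant. HSP26 was at least 22.8-fold lower, since neither mutant array lay above background there, so its rank against CPR6 is not settled. CPR6 (YLR216C), an Hsp90-binding prolyl isomerase, went from 640 ± 80.6 to 27.7 ± 15.2 (SD, n = 2 each), a 24.0-fold difference, and its log2 difference of -4.58 became -5.45 without mutant replicate 1 and -5.37 with median scaling. AHA1 (YDR214W), which stimulates the Hsp90 ATPase, went from 876 ± 40.3 to 74.4 ± 14.2 (SD, n = 2 each), 11.7-fold lower, or -3.55 (log2), and -4.34 with median scaling. The list's camera adjusted p was 3.50e-19 with limma, and adjusted p = 0.191 with an estimated correlation. Its fry adjusted p was 0.0175.

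Within the Hsf1 targets the size of the difference varied widely. The Hsp70 genes SSA1, SSA2 and SSA4 were 7.30-fold, 10.5-fold and 9.32-fold lower, the Hsp90 gene HSP82 9.62-fold, and STI1, which links Hsp70 to Hsp90, 8.85-fold. HSP12 and BTN2, a sorting factor for misfolded proteins, were 11.1-fold and 9.26-fold lower, with HSP12 above background on only 1 mutant array. The metallothionein genes CUP1-1 and CUP1-2 were 7.26-fold and 10.9-fold lower. Without mutant replicate 1 the log2 differences of SSA4, STI1 and BTN2 went from -3.22, -3.15 and -3.21 to -3.95, -3.99 and -4.25, and BTN2 was -2.41 without mutant replicate 2. CUP1-1 and CUP1-2 went from -2.86 and -3.45 to -2.14 and -2.81 without wild-type replicate 2, and CUP1-2 was -4.05 without mutant replicate 2. With median scaling SSA1, SSA2, SSA4, HSP82, STI1, BTN2, CUP1-1 and CUP1-2 were each lower by over 1.5-fold more. With quantile normalization the differences were smaller for the disaggregase gene HSP104 at -1.33 (SE 0.56, log2), the small heat shock protein gene HSP42 at -1.22 (SE 0.41), the polyubiquitin gene UBI4 at -1.21 (SE 0.83) and the endoplasmic reticulum Hsp70 gene KAR2 at -0.77 (SE 0.44). Median scaling gave HSP104 -2.36, HSP42 -2.47 and KAR2 -2.09, and UBI4 was -2.35 without mutant replicate 1 and -0.22 without mutant replicate 2, so the sizes of these 4 are not settled. HSP60 was the 1 member with a higher mean, at 0.50 (SE 1.57), and it lay above background on only 1 array. HSC82 and APJ1 were not above background on any array. All 26 members that were bright by their mean over all 4 arrays were lower. With the 4 members that were dim throughout 1 strain set at their bounds, the median was -2.63. Adjusted over the list alone, 21 of the 30 members were past 0.05 in limma, against 0 adjusted over all genes tested. That count was 0 without wild-type replicate 2, 0 without mutant replicate 2 and 12 without wild-type replicate 1, and members past the fold rule downward numbered 25 to 29 in the 4 fits without 1 array. SSA1 and SSA2, and the CUP1 copies, are near-identical, so their spots can share signal. HSP82 and HSC82 are near-identical too, with wild-type intensities of 201 for HSP82 and 4.42 for HSC82. A spot not above background on any array cannot show whether these genes share signal. HSC82 still counts as past the fold rule downward.

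**Figure D1:**
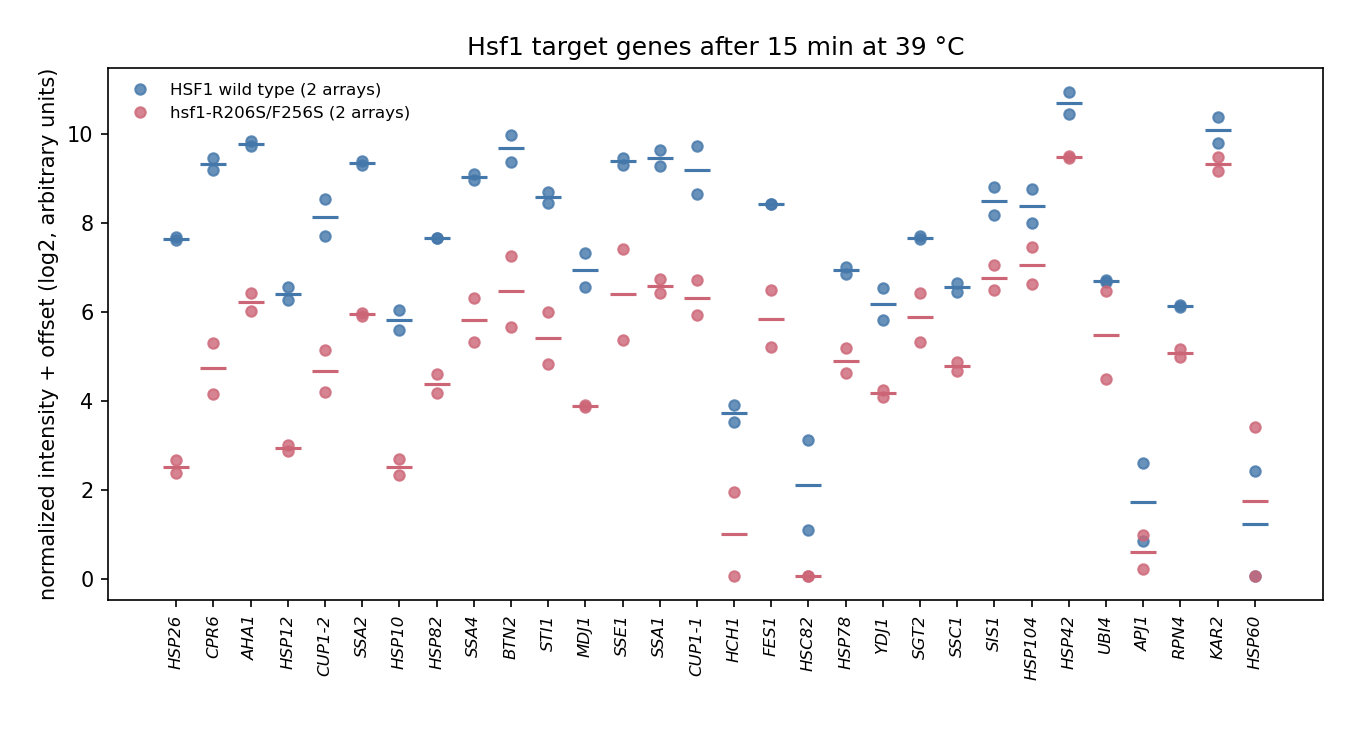
Each point is 1 array's log2 of normalized intensity plus offset (y axis, arbitrary units) for each of the 30 measured Hsf1 targets (x axis), blue for the 2 wild-type arrays and red for the 2 mutant arrays, with bars at the strain means. Genes are ordered by log2 difference with the offset, from HSP26 at -5.11 to HSP60 at 0.50, and 27 of 30 meet the fold rule downward. HSP26 was not above background on either mutant array and HSP60 was on only 1 array, so their exact values are not settled.

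Most chaperone lists held members of both directions. In the cytosolic Hsp70 list, 12 of 18 members were lower, with a median of -1.42 and a camera adjusted p of 0.00337 with limma (adjusted p = 0.273 with an estimated correlation), and fry ended the call (0.0538). The median was -2.57 over the bright members alone. 9 members met the fold rule downward, among them SSA3, at least 6.53-fold lower, and the nucleotide exchange factor FES1, 5.94-fold lower, or -2.57 (log2), and -3.43 without mutant replicate 1. Most of these 9 are also Hsf1 targets. 3 members met the fold rule upward. SSB1, a ribosome-bound Hsp70, went from 43.4 ± 5.89 to 614 ± 311 (SD, n = 2 each), 13.0-fold higher, or 3.70 (log2), with 4.31 without mutant replicate 2 and 2.83 with median scaling. SSB2 was at least 1.70-fold higher and SSZ1, part of the same ribosome-associated system and named after its value was seen, 2.12-fold higher. Adjusted over the list alone, 7 members were lower and 1, SSB1, higher in limma, against 0 over all genes. The lower count was 0 without wild-type replicate 2, 0 without mutant replicate 2 and 2 without wild-type replicate 1, and SSB1 was called in 1 of these 4 fits, that without mutant replicate 1.

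The disaggregase, small heat shock protein and sorting list fell as a whole. All 7 measured members met the fold rule downward, with a median of -3.21 and a camera adjusted p of 5.02e-07 with limma (adjusted p = 0.191 with an estimated correlation). HSP30, a plasma membrane heat shock protein, was at least 10.2-fold lower, and HSP31, named after its value was seen, 2.66-fold lower. The other measured members are all Hsf1 targets too, and the list was not tested without them. Adjusted over the list alone, 5 members were past 0.05, and 3 without wild-type replicate 2, 3 without mutant replicate 1 and 2 without mutant replicate 2. In the Hsp90 list 6 of 13 members met the fold rule downward, all of them also Hsf1 targets, and 2 upward. CPR6, AHA1, HSP82 and STI1 were the 4 members past 0.05 over the list alone, while SBA1, CPR7 and CDC37, named after their values were seen, differed by -0.37 (SE 0.36), 0.07 (SE 0.42) and 0.87 (SE 0.69). The median of the list was -0.37, or -1.0 with median scaling and -0.15 without an offset, and the camera adjusted p 0.0353 with limma (adjusted p = 0.273 with an estimated correlation). This call ended with the replicate block (0.0517), without wild-type replicate 1 (0.100) and without wild-type replicate 2 (0.179), and each of the last 2 fits left 0 members past 0.05 over the list alone.

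Of the mitochondrial chaperones, 5 of 14 members met the fold rule, all downward, and all 5 were past 0.05 adjusted over the list alone. HSP10, the co-chaperonin, was at least 6.43-fold lower. MDJ1, a mitochondrial Hsp40, went from 127 ± 46.7 to 13.7 ± 0.235 (SD, n = 2 each), 8.35-fold lower. HSP78 was 4.06-fold, the import motor Hsp70 gene SSC1 3.42-fold and YTA12 at least 1.58-fold lower. All of these 5 but YTA12 are also Hsf1 targets. MGE1, the nucleotide exchange factor of Ssc1 and named after its value was seen, differed by -0.05 (SE 0.39). The list's median was -0.39, and -0.13 without wild-type replicate 1, -0.73 without wild-type replicate 2, -1.0 without mutant replicate 1, -0.05 without an offset, 0.23 as deposited and -1.90 over the bright members. Its camera adjusted p was 0.0164 with limma (adjusted p = 0.273 with an estimated correlation), and the call ended with fry (0.0538), without wild-type replicate 1 (0.239) and without mutant replicate 2 (0.0868). The list-alone count was 2 without wild-type replicate 1 and 0 without each of the other 3 arrays. For folding in the endoplasmic reticulum, 8 of 15 members were lower, with a median of -0.04 and a camera adjusted p of 0.658 with limma. ERJ5 was 2.63-fold higher. ERO1, the oxidase of disulfide formation and named after its value was seen, was 2.51-fold lower, or -1.33 (log2), and -2.27 with median scaling. For the chaperonin TRiC and prefoldin, 8 of 14 members were higher, with a median of 0.20 and a camera adjusted p of 0.384. The median was -0.03 without mutant replicate 1, 0.42 without wild-type replicate 1 and 0.49 without mutant replicate 2. 9 of these 14 were not above background on both arrays of either strain.

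Genes of the general stress response, which the activators Msn2 and Msn4 drive, also fell. Of 34 measured members 32 were lower and 20 met the fold rule, all downward, with a median of -1.39. SPI1, a cell wall protein gene, went from 1264 ± 412 to 167 ± 9.53 (SD, n = 2 each), 7.34-fold lower. HXK1, a hexokinase gene, was 5.27-fold lower. Chosen after their values were seen, PGM2, a phosphoglucomutase gene, was 4.52-fold lower, and the catalase gene CTT1 went from 459 to 138, 3.30-fold lower. PGM2 went from -2.18 (log2) to -2.79 without mutant replicate 2, and median scaling took SPI1, HXK1 and CTT1 from -2.88, -2.40 and -1.72 to -3.89, -3.09 and -2.77. The camera adjusted p was 3.90e-12 with limma (adjusted p = 0.191 with an estimated correlation), and the fry adjusted p was 0.000392. Adjusted over the list alone, HSP26, HSP12, SPI1 and HXK1 were past 0.05, and 0 members were in any of the 4 fits without 1 array. HSP12 and HSP26 are also on the Hsf1 list. Without them the median of the other 32 members was -1.38, with 18 members past the fold rule.

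Cytosolic ribosomal protein genes rose as a list. Of 131 measured cytosolic ribosomal protein genes 113 had a higher mean in the mutant, 74 met the fold rule upward and 4 downward, with a median of 1.27. Among the 85 bright by their mean over all 4 arrays, 82 were higher. The median was 0.95 with 29 members set at their bounds. RPL4A was at least 3.63-fold higher, and RPL2A, above background on only 1 wild-type array, 8.80-fold higher. Without wild-type replicate 1 and without wild-type replicate 2 the log2 difference of RPL2A went from 3.14 to 3.98 and 2.15. Named after their values were seen, RPL8A was 8.11-fold higher, RPS9B 6.38-fold and RPL3, which has no paralog, 4.84-fold, from 61.1 to 307. Median scaling took RPL8A, RPS9B and RPL3 from 3.02, 2.67 and 2.28 (log2) to 2.35, 2.02 and 1.45. The camera adjusted p was 2.06e-15 with limma (adjusted p = 0.191 with an estimated correlation), and the fry adjusted p was 0.0205. No member was past 0.05 over the list alone or over all genes. Paralogous pairs can share signal on these arrays.

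Ribosome biogenesis genes passed camera but not fry (0.192), and most were dim in the wild type. 32 of 43 members were higher, 12 met the fold rule upward and 2 downward, and the median was 0.93, and 0.51 without wild-type replicate 1, 0.49 without mutant replicate 1, 1.47 without mutant replicate 2, 0.48 with the larger offset, 1.60 over the members above background and 0.36 over the bright members. With 28 members set at their bounds the median was 0, so the size of this shift is not determined. DBP3, NOP12 and NOP58 were past 0.05 over the list alone, with mutant intensities of 13.7, 14.5 and 12.7 and no wild-type array above background, and 0 members were in any fit without 1 array. The camera adjusted p was 0.00115 with limma (adjusted p = 0.273 with an estimated correlation), and it was 0.179 without mutant replicate 1. Genes of amino acid biosynthesis rose, with 35 of 44 higher, 16 past the fold rule upward and 2 downward, a median of 0.75, or 1.28 as deposited, and a camera adjusted p of 0.000537 with limma (adjusted p = 0.191 with an estimated correlation). MET14, the kinase of sulfate assimilation, was at least 2.92-fold higher. With 15 members at their bounds the median was 0.20.

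Most genes of the energy metabolism lists were lower. Of 42 genes of the respiratory chain and TCA cycle 34 were lower, 17 met the fold rule downward and 1 upward, with a median of -0.69, or -0.30 as deposited, and a camera adjusted p of 0.000115 with limma (adjusted p = 0.191 with an estimated correlation), a call that ended with fry (0.0538). SDH3, a subunit of succinate dehydrogenase and above background on only 1 mutant array, was 5.78-fold lower. ATP15, a subunit of the ATP synthase, differed by -2.16 (SE 1.02), and by -1.07 without mutant replicate 1, -3.33 without mutant replicate 2 and -1.52 without wild-type replicate 2. In glycolysis and fermentation 13 of 17 genes were lower, with a median of -0.46, from -0.24 without wild-type replicate 1, -0.28 without mutant replicate 1 and -0.29 with cyclic loess to -0.71 without wild-type replicate 2, -0.77 without mutant replicate 2 and -1.22 with median scaling (adjusted p = 5.85e-07), and an adjusted p of 0.0433 with limma (adjusted p = 0.273 with an estimated correlation). PFK2, above background on only 1 mutant array, was 3.03-fold lower, or -1.60 (log2), and -0.97 as deposited. TPI1 was 2.91-fold lower. This call ended without wild-type replicate 1 (0.239), without mutant replicate 1 (0.0525) and without mutant replicate 2 (0.105), and also with cyclic loess (0.129), the replicate block (0.0707) and fry (0.210).

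**Figure D2:**
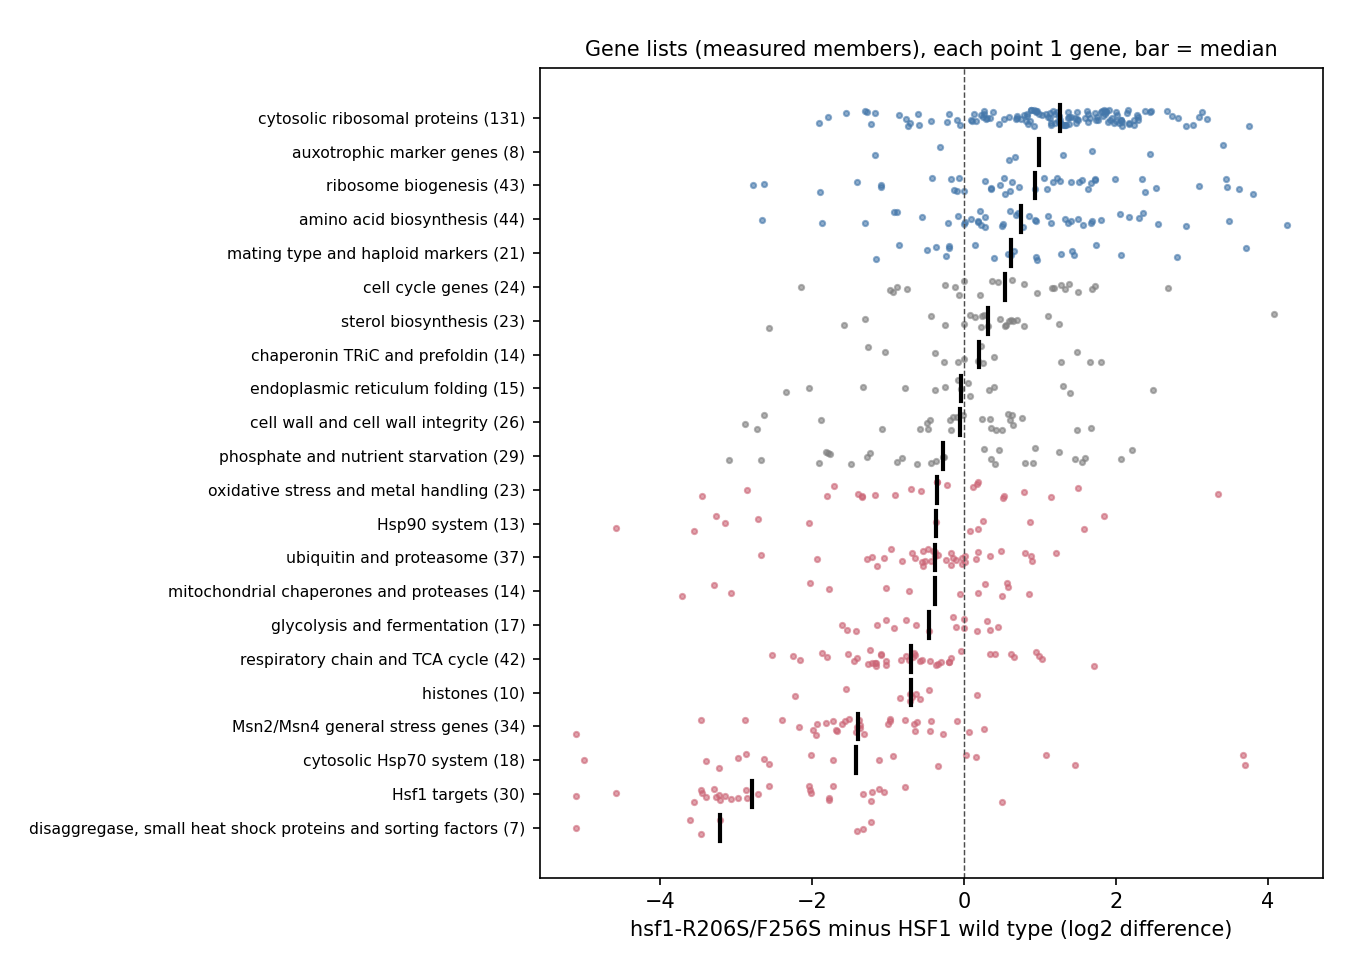
Each point is 1 gene's log2 difference, mutant minus wild type (x axis), in each of the 22 gene lists (y axis, measured members in parentheses), and black bars are list medians. Red lists are lower and blue lists higher at a camera adjusted p under 0.05 with the preset correlation, and grey lists are not past it. Medians run from -3.21 for the disaggregase list to 1.27 for ribosomal proteins.

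Among the remaining lists, ubiquitin and proteasome genes had a median of -0.38, or -0.20 without wild-type replicate 1, -0.22 without mutant replicate 2, -0.24 over the bright members, -0.57 without mutant replicate 1, -0.70 with median scaling (adjusted p = 0.000657) and -0.04 as deposited, with 27 of 37 lower and a camera adjusted p of 0.0423 with limma (adjusted p = 0.436 with an estimated correlation). RPN4, the activator of proteasome genes, was 2.07-fold lower. This call ended without wild-type replicate 1 (0.239), without mutant replicate 2 (0.360), and with cyclic loess (0.0514), the replicate block (0.0648), bright genes alone (0.107) and fry (0.249). The oxidative stress and metal list had a median of -0.36, or -0.54 without mutant replicate 2, -0.87 with median scaling (adjusted p = 0.00333) and -0.24 as deposited, and an adjusted p of 0.0384 (adjusted p = 0.273 with an estimated correlation), with 14 of 23 lower. Its largest decreases were the CUP1 genes and the peroxiredoxin gene AHP1, 3.47-fold lower, or -1.80 (log2), and -3.11 with median scaling. The call ended with the replicate block (0.0648), without wild-type replicate 1 (0.239) and without mutant replicate 2 (0.0699). Histone genes had a median of -0.69, or -1.05 with median scaling and -0.34 as deposited, and an adjusted p of 0.0126 (adjusted p = 0.273 with an estimated correlation), with 9 of 10 lower, HTA2 2.92-fold lower, but the call ended without wild-type replicate 1 (0.147) and with fry (0.192). The cell wall list did not pass, with a median of -0.05 and an adjusted p of 0.647. It held genes of both directions, since TIP1 was 6.61-fold and CWP1 6.20-fold lower, and UTR2, named after its value was seen, 3.20-fold higher. TIP1 went from -2.73 (log2) to -3.41 without mutant replicate 1 and with median scaling, which took CWP1 from -2.63 to -3.24 and UTR2 from 1.68 to 0.97. The list passed with median scaling (0.0141) and on the values as deposited (0.0403). Cell cycle genes (median 0.54, adjusted p = 0.0706), sterol genes (median 0.32, adjusted p = 0.241) and phosphate and nutrient genes (median -0.28, adjusted p = 0.490) did not pass. Their medians were 0.04 for cell cycle genes without wild-type replicate 1, and 0 for phosphate and nutrient genes without wild-type replicate 1 or mutant replicate 1. The sterol median was 0.07 without wild-type replicate 2 and 0.60 without mutant replicate 2. With 9 members at their bounds the cell cycle median was also 0. Among nutrient genes PUT1, the proline oxidase gene, went from 87.5 ± 7.57 to 369 ± 39.9 (SD, n = 2 each), 4.17-fold higher, or 2.06 (log2), and 1.09 with median scaling. Cell cycle genes had an adjusted p of 0.0475 without mutant replicate 1.

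The HSF1 spot itself was far brighter in the mutant. Deposited intensities of HSF1 were 33.2 and -7.56 on the wild-type arrays and 462 and 429 on the mutant arrays. Its log2 difference was 6.52 (SE 1.98), and 3.67 without wild-type replicate 2, where it lay below background, and 8.93 without wild-type replicate 1. Since the allele differs by amino acid changes, this level does not check the labels. TRP1 (YDR007W), a gene of tryptophan synthesis often used as a selection marker, went from 37.9 ± 12.9 to 404 ± 43.1 (SD, n = 2 each), 10.6-fold higher, or 3.41 (log2), and 2.60 with median scaling. URA3 was higher by 2.45 (SE 0.38), or 1.00 with the larger offset, but was not above background in the wild type, with a mutant intensity of 4.75. No bound on its fold can be given, so the size of its difference depends on the offset. TRP1 and URA3 were past 0.05 adjusted over the list of 8 marker genes alone, and 0 genes were without wild-type replicate 2, mutant replicate 1 or mutant replicate 2. That list had a median of 0.99, or 0.47 without wild-type replicate 2, 1.66 as deposited, 0.59 over the bright members and 0 with 4 members at their bounds, and a camera adjusted p of 0.0450 with limma (adjusted p = 0.273 with an estimated correlation). The call ended in each fit without 1 array, with 0.0837 and 0.191 for the wild-type arrays and 0.212 and 0.218 for the mutant arrays. It also ended (0.0514 to 0.330) with median scaling, as deposited, with cyclic loess, without an offset, with the larger offset, with the replicate block, with values below 0 missing, without the dimmest genes, and on genes above background or bright. Mating type and haploid genes had a median of 0.62, or 0.09 without wild-type replicate 1, 0.28 without mutant replicate 1, 0.36 with the larger offset, 1.27 as deposited and 0 with 6 members at their bounds, and an adjusted p of 0.0353 (adjusted p = 0.273 with an estimated correlation), with 14 of 21 higher. The largest 2 increases were in genes of α cells. SAG1, the α-agglutinin gene and its 1 member past 0.05 over the list alone, was at least 1.99-fold higher. MF(ALPHA)2, an α-factor gene above background on 1 wild-type array, was 6.98-fold higher, and its log2 difference went from 2.80 to 1.61 without wild-type replicate 2, 3.85 without wild-type replicate 1 and 3.49 without mutant replicate 1. AGA2, an agglutinin gene of a cells, came next at 2.07 (SE 0.62) but was not above background on any array. The mating type call ended without wild-type replicate 1 (0.239), without mutant replicate 2 (0.105), with median scaling (0.0845), the replicate block (0.0517), genes above background (0.131) and bright genes (0.107), and 0 members were past 0.05 over the list alone in any fit without 1 array.

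**Figure D3:**
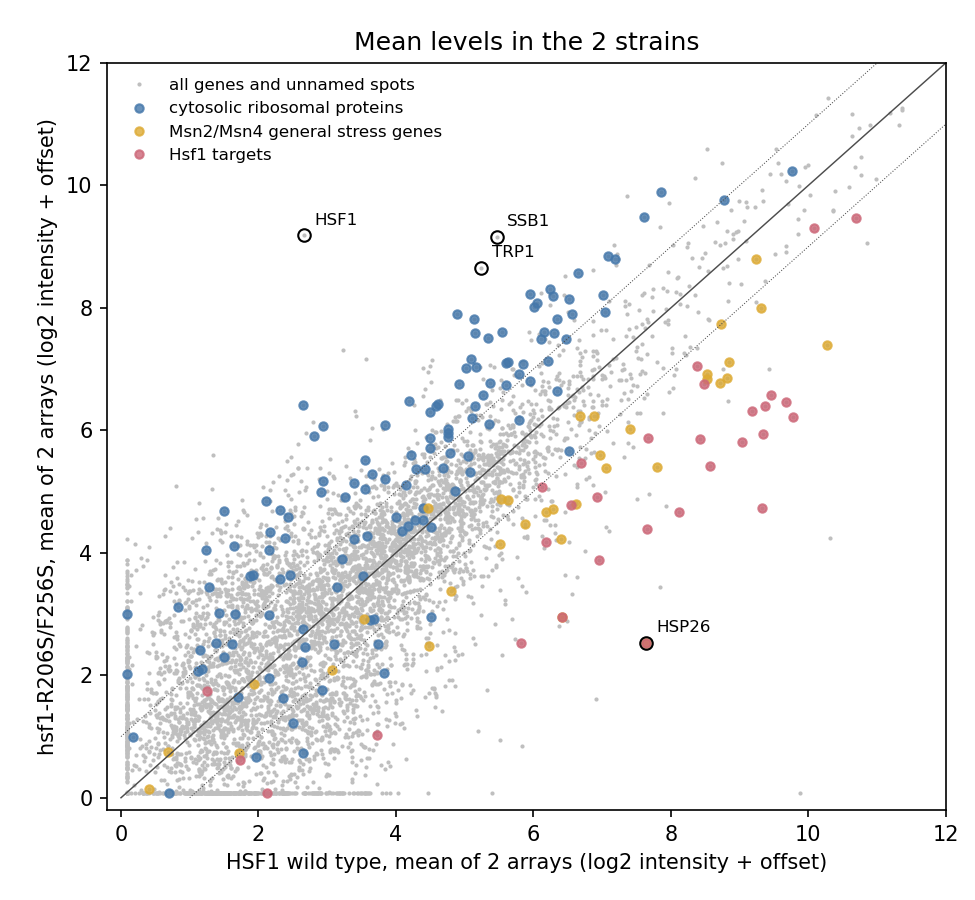
Each point is 1 gene's mean log2 level over 2 wild-type arrays (x axis) and 2 mutant arrays (y axis), in normalized intensity plus offset (arbitrary units), with a solid line at equality and dotted lines at 2-fold. The median differences of Hsf1 targets (-2.78) and Msn2/Msn4 genes (-1.39) are below 0 and that of ribosomal protein genes (1.27) above 0, with 1, 2 and 18 members on the other side of the line, and circles mark HSF1, TRP1, SSB1 and HSP26.

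Gene by gene, 818 genes met the fold rule upward and 772 downward. In simulation 784.5 unchanged genes per run met it as well, so many of these genes need not differ. 40.4% of genes did not overlap between the strains, where chance gives 33.3%. Among the 2220 genes bright over all 4 arrays 283 met the rule upward and 220 downward, with 50.8% not overlapping. Among genes above background the counts were 469 and 228, but that filter uses the strains and the mutant arrays had lower limits, so its upward excess is not a finding. On the values as deposited the split was 1700 upward and 338 downward, with the median of all genes shifted by 0.63 (log2). The largest decreases above the median level were YER138C, a Ty1 transposon reading frame, and YAR009C, another Ty1 reading frame, but both include deposited values of exactly 0 on mutant arrays. YER138C was 810 and 1423 on the wild-type arrays and listed at 0 on both mutant arrays, and YAR009C was listed at 0 on mutant replicate 1. TMA10, a gene of a small ribosome-associated protein, was 21.2-fold lower, from 229 ± 1.93 to 10.1 ± 3.92 (SD, n = 2 each). HSP26, SSA3 and CPR6 ranked above TMA10 by log2 difference. Neither HSP26 nor SSA3 was above background on a mutant array, so the place of these 2 is not settled. SEC14, YPL162C and ADK2 ranked among the 10 largest decreases through a bright spot on wild-type replicate 2 alone, and without that array their log2 differences were -1.70, -1.54 and -0.40. Of the 10 largest increases PPH21, MET14, SAG1 and SSB2 were not above background on either wild-type array, and PPH21, a phosphatase gene, was at least 2.06-fold higher. ERG13, RPL10 and the unnamed spot probe_3308 were below background on wild-type replicate 2 only, where probe_3308 was listed at 0, and without that array their log2 differences were 0.83, 1.10 and 1.48.

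In limma's main test 0 genes were higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 0.277. At an unadjusted p under 0.05 there were 345 higher and 365 lower genes, 710 in all against 302.55 given by chance. On the 2220 bright genes with an intensity trend, a fit chosen after seeing the data, limma called 34 higher and 43 lower genes. The 43 lower genes held 17 Hsf1 targets and 8 Msn2/Msn4 genes, and the 34 higher genes held 16 ribosomal protein genes. The smallest adjusted p in that limma fit, 0.000497, was that of YER138C with its mutant values of exactly 0. After it came HSP26 (adjusted p = 0.00576) and SSA2, AHA1 and TMA10 (adjusted p = 0.00942 each), all lower, and among higher genes TRP1 (adjusted p = 0.0159) came first. SSB1 was also higher (adjusted p = 0.0198), and each of these genes lay on its stated side on both mutant arrays. On genes above background the same fit called 19 higher and 37 lower genes, with the limit that this filter uses the strains. 16 of the 22 lists passed camera with the preset correlation and 0 with an estimated correlation. 9 passed fry, which tests a list's genes without comparing them with others. The 0 does not show that members vary together, since that form of camera has only 2 residual degrees of freedom. For Msn2/Msn4 genes the estimated correlation was -0.0176, below the preset, yet the unadjusted p of that camera test was 0.0141. Some lists share members, above all the chaperone lists with the Hsf1 targets, so these calls are not separate results.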

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

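The sign of a named gene's difference turned in 1 case under the alternatives and 2 without 1 array. The main test called 0 genes and recovered 0% in simulation, so its threshold says nothing of their stability. An intensity trend, robust moderation, the replicate block and the subsets of genes leave a gene's difference unchanged, so no sign could turn there. Direction of a list here is the sign of its test, which can differ from that of its median. The list tests do not use the intensity trend, robust moderation or array weights. Settings that differ only in these repeat one another by construction in the list counts under the alternatives. Under the alternatives the lists kept direction and side of the threshold in 363 cases, lost the call in 49, gained it in 2 and turned in 4. Without 1 array these were 65, 19, 1 and 3. Of 93 genes followed, median scaling moved 40 by over 1.5-fold, 38 of them down, and the larger offset moved 26. Leaving out 1 array moved 18 to 25. Where a result changed, the cause was not tested, except that the settings on fewer genes count fewer by construction. With both strains numbered 1 and 2, arrays share only a number, since the labels tie it to nothing. The replicate deviations correlated at 0.0196 between strains, and 2 pairs are too few to tell. Signal over background limits the dim genes. Fits without 1 array leave 1 sample in a strain, assumed to vary like the other strain.

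The fold rule gave 1700 higher and 338 lower genes as deposited, 510 and 446 without an offset, 501 and 426 with an offset of the 25th percentile, 469 and 228 on genes above background and 283 and 220 on bright genes, each with or without an intensity trend, and 544 and 467 with values below 0 missing. In limma's adjusted test the intensity trend called 1 lower gene, genes above background 1 lower, and both together 19 higher and 37 lower, though this filter uses the strains. Bright genes gave 1 higher and 11 lower, and with the trend 34 higher and 43 lower. With or without the trend, bright genes gave camera adjusted p-values of 0.107 for the proteasome and for mating type and 0.226 for marker genes, all missed, and the sign of the test turned, without passing, for endoplasmic reticulum folding (0.760, median 0.08) and the chaperonin list (0.903, though its median stayed above 0 at 0.23). In camera, cell wall genes passed with median scaling (0.0141) and as deposited (0.0403, with a list median of 0.10). Mating type genes missed with median scaling (0.0845) and above background with or without the trend (0.131). Marker genes missed with median scaling (0.0722), as deposited (0.0514), cyclic loess (0.0800), no offset (0.178), the 25th percentile offset (0.0565), the dimmest 25% removed (0.203), above background (0.330) and values below 0 missing (0.167). With cyclic loess the proteasome list (0.0514) and glycolysis (0.129) missed. With the replicate block, Hsp90 and mating type (0.0517 each), proteasome, oxidative stress and marker genes (0.0648 each) and glycolysis (0.0707) missed, and no other call changed. That block left 14 Hsf1 targets past 0.05 over the list alone, against 21.

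With an estimated correlation the adjusted p was 0.191 for Hsf1 targets, disaggregase, Msn2/Msn4, ribosomal protein, respiratory and amino acid genes, 0.436 for the proteasome, and 0.273 for Hsp70, Hsp90, mitochondrial chaperones, ribosome biogenesis, glycolysis, oxidative stress, histones, mating type and marker genes. fry gave 0.0538 for Hsp70, mitochondrial chaperones and respiratory genes, 0.192 for ribosome biogenesis and histones, 0.249 for the proteasome and 0.210 for glycolysis. APJ1 turned to 0.36 (log2) as deposited, where the median of all genes was 0.63.

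Without 1 array, adjusted p-values ranged from 4.25e-17 to 7.73e-10 for Hsf1 targets, 0.0374 to 0.179 for Hsp90, 0.0104 to 0.239 for mitochondrial chaperones, 0.00575 to 0.360 for the proteasome, 0.00012 to 0.179 for ribosome biogenesis, 0.0166 to 0.239 for glycolysis, 0.0347 to 0.239 for oxidative stress, 0.00479 to 0.147 for histones, 0.0199 to 0.239 for mating type, 0.0837 to 0.218 for marker genes and 0.0475 to 0.437 for cell cycle genes. The sign of the test turned without passing for cell wall genes (0.513 to 0.945, turned without wild-type replicate 1 at 0.648, while the median was above 0 without each array but wild-type replicate 2), sterol genes (0.0596 to 0.913, turned without wild-type replicate 2 at 0.913, with a median of 0.07) and endoplasmic reticulum folding (0.533 to 0.950, turned without mutant replicate 2 at 0.950). HSP60 ranged from -1.13 to 2.17 and was -0.72 without wild-type replicate 2. Fold-rule counts ranged from 1049 to 1282 higher and 999 to 1394 lower, the highest of each without wild-type replicate 1.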

Other observations

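5 further lists were chosen and tested after seeing the data, and the genes named from them and YER160C after their values were seen. Cytosolic translation factors had a median log2 difference of 0.81, with 21 of 26 higher and 10 past the fold rule upward, and a camera adjusted p of 0.00205 with limma (adjusted p = 0.267 with an estimated correlation), but did not pass fry (0.154). YEF3, elongation factor 3, was 5.20-fold higher, or 2.38 (log2), with 1.64 and 1.77 without replicate 2 of the wild type and of the mutant and 2.99 and 3.16 without replicate 1 of each. TIF1, a helicase of translation initiation, was higher by 1.63 but by only 0.34 with median scaling. Cytosolic tRNA synthetases had a median of 1.39, with 16 of 19 higher, 11 past the fold rule upward and 2 downward. The camera adjusted p was 0.00122 with limma (adjusted p = 0.184 with an estimated correlation), but the list did not pass fry (0.0699). Of those past the rule, FRS2, HTS1, THS1, ILS1 and CRS1 upward and GUS1 downward were dim throughout at least 1 strain. They have neither a fold nor a bound, and TYS1 was at least 1.43-fold higher. KRS1, the lysyl-tRNA synthetase gene, was 3.51-fold higher. Purine and pyrimidine genes did not pass, with a median of 0.82 and an adjusted p of 0.0899.

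Trehalose and glycogen genes had a median of -0.78, with 13 of 15 lower and a camera adjusted p of 0.00205 with limma (adjusted p = 0.184 with an estimated correlation), but did not pass fry (0.0699). UGP1, which makes UDP-glucose, was 3.43-fold lower. Most of these 15 genes are also on the Msn2/Msn4 list. Mitochondrial ribosomal protein genes went against the cytosolic ones, with a median of -0.40 and 30 of 42 lower. The camera adjusted p was 0.0337 with limma (adjusted p = 0.184 with an estimated correlation), and the list passed fry (0.0253). 6 genes were past the fold rule downward and 1 upward. Of the 6, MRPL25 was 2.04-fold lower and MRPS8 at least 1.44-fold lower. MRPS17, MRPL33, MRPS28 and MRPL37, and MRPL22 upward, were dim throughout at least 1 strain and have neither a fold nor a bound. The size of this shift is therefore not determined. The opposite sign of the 2 ribosomal protein lists was not itself tested. Other Ty reading frames were bright on all 4 arrays. YER160C was deposited at 1285 and 1569 in the wild type and 573 and 682 in the mutant, so the values of exactly 0 for YER138C on both mutant arrays stand apart from it, and no cause was tested.

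HSF1 and TRP1 were both far brighter in the mutant, with log2 differences of 6.52 and 3.41. The tests of a defect on 1 array, of an added TRP1 copy and of the region around HSF1 as the whole cause were chosen after the result was seen. A gained chromosome region around TRP1 is argued against by its 10 neighbouring genes, whose median was -0.352, and around HSF1 as the whole cause by a neighbour median of 0.825 (SE 0.343) against an HSF1 difference of at least 3.67 without 1 array. A defect on 1 array is argued against by the smallest difference of either gene without 1 array, 2.97, for TRP1. A smaller gain around HSF1 cannot be told apart from none with a neighbour median of 0.825, and a mutant allele carried with an added TRP1 copy may also account for both genes, but the other 7 marker genes had a median of 0.672 with a wide spread and the labels do not describe the strains.

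The rise of ribosomal protein genes was set against 4 technical explanations. The choice among 4 scalings is argued against by the smallest median relative to all genes, 0.884. That measure takes out a shift shared by all genes, so it does not test such a shift. A trend with brightness is argued against by a median at percentile 100 of 10000 lists matched on level (highest random median 0.427). Against the array of wild-type replicate 2 stands a median of 1.02 without it. Against signal shared between paralogs stands a median of 1.63 over 17 genes without a paralog. The strain difference named in the design stays open, as does a difference between cultures or hybridisations of the 2 strains, and neither was tested.

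The fall of Msn2/Msn4 genes was set against 3 explanations. The fall does not rest on the 2 members shared with the Hsf1 list, since the other 32 had a median of -1.38 (SE 0.164). Any Hsf1-driven genes outside that list were not removed, so a wider overlap was not tested. A trend with brightness is argued against by percentile 0 of 10000 matched lists (lowest random median -0.639). The choice among 4 scalings is argued against by a largest median relative to all genes of -1.41. That measure again takes out a shift shared by all genes and does not test it. The strain difference named in the design and a difference between cultures of the 2 strains stay open, and neither was tested.

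The 4 arrays can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. The real split gave 1590 genes past the fold rule and the highest other split 1006, so that 1 of 3 splits, the real one, was as large. On genes bright over all 4 arrays, a test chosen after the result was seen, the values were 503 and 123, again 1 of 3. On genes above background, also chosen afterwards, they were 697 and 174, again 1 of 3, but that filter uses the real strains and so favours the real split. For lists past camera they were 16 and 0, again 1 of 3. The median of the Hsf1 targets was -2.78 in the real split and -0.08 and 0.20 in the others. Each other split puts 1 wild-type and 1 mutant array in both groups, so a difference between strains cancels there by construction. The values of the other splits therefore do not show what unchanged strains would give.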
